A study of Arabidopsis thaliana with 12 samples.

How the data were processed

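Gene expression was measured on 12 one-colour Agilent arrays, 1 per sample, in seedlings of Arabidopsis thaliana. The labels gave 4 groups of 3 arrays: wild type Col-0 and the double mutant cry1cry2, each grown on the solvent dimethyl sulfoxide (DMSO) or on 15 µM 3-bromo-7-nitroindazole (3B7N). The series text speaks of 3 chemicals, and 1 of them is in these samples. Nothing in the labels says whether the samples of a group came from separate cultures, so each p-value below measures the spread between these samples.

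Per the file headers, the authors extracted the signal of each spot with Agilent Feature Extraction 10.7.3.1, and the deposited intensity used here is the background-subtracted, spatially detrended processed signal, which was not scaled between arrays. Per the file headers, the raw median intensity of each spot and of its local background is also given, with flags for spots well above background, saturated or non-uniform. The authors also deposited a list of probes with a fold change without a sign and a corrected p-value for each chemical contrast. The correction, the scaling and the filter behind that list are not given in the sources used here. Its values were used only for a comparison with the fit described next.

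Each array held 45220 spots, of which 43803 were not controls and stood for 43603 probes, and 50 probes had several spots. Spots of 1 probe were averaged on the log2 scale, and 49 probes with an outlier spot were left out. The log2 processed signal of each array was set relative to its 75th percentile. A probe was kept where it was well above background on all 3 arrays of at least 1 group. Probes were joined to loci through the RefSeq transcript accession that the array files give, in a table of the TAIR10.1 assembly, which also gave the gene symbols. The headers name the earlier release TAIR10, so no coordinates are given. A locus was found for 34348 probes and none for 9255. The probes covered 25410 loci, and 6946 loci had several probes. The kept probe with the highest mean signal over all arrays stood for its gene, which left 20487 genes from 28504 kept probes. Several kept probes were present for 6170 genes. Near-identical paralogs (members of LHCB1, RBCS, SAUR19 to SAUR23, GSTF6 and GSTF7, seed albumins and small heat shock proteins) may share signal, and their single values are uncertain for that reason.

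Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of 4 group means to all 12 arrays, with Benjamini-Hochberg adjustment over the 20487 genes. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Arrays give no counting depth, and the number of arrays limits the precision. Where no probe of a gene was well above background on any array of a group, the fold is given as "at least N-fold", computed against the lowest signal that was flagged well above background on each array. For PORA, CRY1 and CRY2 it is given for single probes. The contrasts were 3B7N against DMSO in wild type, 3B7N against DMSO in the mutant, mutant against wild type on DMSO, mutant against wild type on 3B7N (as counts), and the interaction, which is the change with 3B7N in the mutant minus that in wild type. All tests by limma are two-sided.

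A set of 23 gene lists with 429 entries (425 loci) was tested in each contrast with camera of limma at its preset correlation of 0.01, with adjustment over the lists of a contrast. Camera with an estimated correlation was run beside it. The lists were photoreceptors, photomorphogenesis regulators, the flavonoid and anthocyanin pathway, light harvesting and photosynthesis, chlorophyll biosynthesis, photoprotection and carotenoids, auxin response, PIF and shade response, cell wall expansion, brassinosteroid and gibberellin, abscisic acid and water stress, ethylene, the circadian clock, dark and sugar starvation, xenobiotic detoxification, nitrate assimilation and nitric oxide, reactive oxygen response, defence and jasmonate, glucosinolate biosynthesis, seed storage and lipid mobilisation, cell division, root-preferred markers, and housekeeping genes. The gene table did not hold 15 of the list symbols, which were matched by locus, and 2 list members were not on the array. The lists, their tests, the thresholds and the alternatives were chosen before the data were examined, apart from those named as added or chosen later.

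Genes were named by a rule that was also fixed then. It covers the 8 highest and 8 lowest called genes of the first 3 contrasts whose groups do not overlap and that have a gene symbol, up to 4 members of each list with the smallest adjusted p, the 5 highest and 5 lowest called genes with a symbol in the interaction, all members of a count of 5 or fewer, and CRY1, CRY2, HY5, HYH, COP1, PIF4, PIF5, CHS and the housekeeping genes. Loci without a symbol, some of them with larger values, are left out of these ranks. A gene outside this rule is named as chosen after its values were seen.

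The steps were first tested on simulated data made from the 20487 genes with 50 genes changed by each fold. In the contrast of 3B7N in wild type, 0% of the genes changed 1.5-fold were called, 52% at 2-fold, 90% at 3-fold and 96% at 4-fold, with 6 unchanged genes called. In the mutant the shares were 2%, 36%, 78% and 86% (5 unchanged genes called), between genotypes on DMSO 0%, 48%, 82% and 92% (1 unchanged gene), and for the interaction 2%, 12%, 64% and 72% (6 unchanged genes). A list of 25 genes shifted by 0.5 log2 was called by both camera settings in the wild-type contrast, and 0 of the other lists was called at the preset correlation. The simulated genes varied independently, so this does not test the preset correlation on lists whose genes vary together. In the real data the estimated correlation was 0.704 for light harvesting.

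The headers place the arrays on 3 slides of 4, and the scan passes divide them the same way. Slide 1 held the 3 wild-type DMSO arrays and 3B7N array 1 of wild type. Slide 2 held wild-type 3B7N arrays 2 and 3 and mutant DMSO arrays 1 and 2, and slide 3 held mutant DMSO array 3 and the 3 mutant 3B7N arrays. Slide was therefore also fitted as a block, and the change with 3B7N was computed within slide 1 and within slide 3. The slide-block coefficient of the wild-type contrast equals the value within slide 1, which rests on 1 treated array. That of the mutant contrast equals the value within slide 3, which rests on 1 DMSO array. The genotype contrasts with a slide block are chained through slide 2.

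Alternatives were quantile and median scaling, normexp background correction with an offset of 50, no filter and a filter on all 12 arrays, the mean of a gene's probes, fits of the compared groups alone, array weights, eBayes with trend and robust, blocks for replicate number, slide and scan pass, leaving out each array, adjusted p alone, an adjusted p under 0.01, and limma's treat at a log2 difference of 0.5. The normexp alternative had been planned with the mean spot signal. The files used here hold the median, which took its place. Slide as a random block, and leaving out 2 mutant arrays together, were added after the data were examined. Fisher's exact test (one-sided) over 213 families of gene symbols with at least 8 members was also added then. It ran on 8918 named genes in 426 tests per contrast with Benjamini-Hochberg adjustment. Correlations between contrasts are across genes, which are not independent replicates. Simulated groups without any change (100 draws) gave the correlation and covariance that shared arrays produce. Other tools were data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Probes without a locus were left out of the gene tests and are given as counts.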

Results

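Expression was compared in 4-day-old seedlings kept for 3 days in the dark and cold and then for 4 days in blue light of 5 µmol m-2 s-1, with or without 3B7N, a compound known as an inhibitor of nitric oxide synthase in mammals. The study's title concerns hypocotyl elongation induced by chemicals in blue light, a light in which the cryptochromes CRY1 and CRY2 normally hold hypocotyls short. The 4 groups held 3 arrays each. The 75th percentile of the processed signal was 1957, 1685 and 2333 in wild type on DMSO and 1920, 882.6 and 2022 in wild type on 3B7N. It was 6794, 2567 and 4202 in the mutant on DMSO and 3198, 4045 and 3186 in the mutant on 3B7N. Between 64.4% (wild type on 3B7N, array 2) and 81.2% (mutant on DMSO, array 1) of the probes were well above background, and 0 spots were saturated. Arrays of 1 group correlated across genes at r = 0.979 to 0.993. The first 3 principal components held 48%, 20.9% and 10.8% of the variance.

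The cryptochrome genes matched the labels on every array. CRY1 (AT4G08920) had relative log2 signals of 3.597, 3.42 and 3.25 in wild type on DMSO and 3.58, 3.86 and 3.70 in wild type on 3B7N. The mutant gave -8.73, -9.85 and -7.90 on DMSO and -7.76, -8.00 and -7.73 on 3B7N. CRY2 (AT1G04400) had 1.85, 2.004 and 2.16 in wild type on DMSO, 2.48, 2.36 and 2.49 in wild type on 3B7N, -8.70, -8.76 and -8.59 in the mutant on DMSO, and -8.94, -8.64 and -8.84 in the mutant on 3B7N. The probes shown were above background on 1 of 3 mutant DMSO arrays each, and on 3B7N that of CRY1 was on 3 of 3 and that of CRY2 on 0. A further probe of each gene, above background on 0 of the 6 mutant arrays, was at least 2260-fold lower for CRY1 and at least 1430-fold lower for CRY2 in the mutant on DMSO. In wild type, 3B7N left CRY1 (log2 difference 0.29 ± 0.36, SE, adjusted p = 0.543) and CRY2 (0.44 ± 0.13, adjusted p = 0.019) short of the call.

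**Figure D1:**
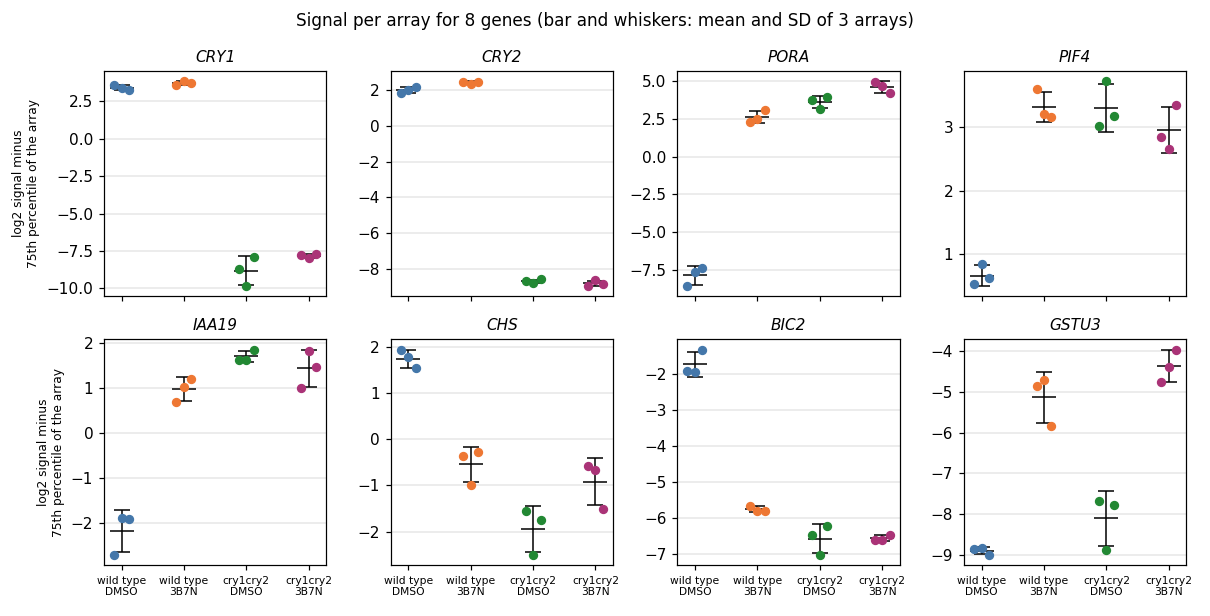
Log2 processed signal relative to the 75th percentile of each array for 8 genes, 1 point per array, with the mean and SD of the 3 arrays of each group. CRY1 and CRY2 separate the genotypes, PIF4 and CHS of treated wild type lie nearer to the mutant than to wild type on DMSO, and GSTU3 is higher on 3B7N in both genotypes.

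The first comparison asked which transcripts 3B7N alters in wild type. Among the genes that rose were factors of growth and of the auxin response. PIF4 (AT2G43010), a factor that promotes hypocotyl elongation, rose by 2.65 ± 0.23 (log2, SE, adjusted p = 1.04e-05), from 0.66 ± 0.16 to 3.31 ± 0.24 (SD, n = 3). PIF5 rose by 1.63 ± 0.19 and the auxin-inducible IAA19 (AT3G15540) by 3.14 ± 0.26, IAA6 by 4.39 ± 0.32 and IAA20 by 4.98 ± 0.28. The wall-loosening gene XTH15 rose by 3.61 ± 0.26, the gibberellin biosynthesis gene GA20OX1 by 3.41 and the sulfotransferase gene ST2A by 3.66 ± 0.28. PORA (AT5G54190), a protochlorophyllide reductase gene normally high in darkness, had the highest value, 10.48 ± 0.34 (adjusted p = 1.5e-08). Its 3 probes gave 10.48, 7.59 and 5.78, and the first was at least 771-fold higher and the last at least 37.2-fold higher, since neither was above background in wild type on DMSO, while the second was on 2 of 3 arrays. PHYA, a photoreceptor whose transcript falls in light, rose by 2.16 ± 0.18. Each of these genes was higher on 3 of 3 treated arrays than on any DMSO array of wild type, and each kept its call with slide as a block, where PIF4 stood at 2.92, IAA19 at 2.85, PHYA at 1.96 and PORA at 10.17.

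Among the genes that fell were inhibitors of the cryptochromes and enzymes of flavonoid synthesis. BIC2 (AT3G44450), 1 of these inhibitors, decreased by 4.05 ± 0.21 (adjusted p = 5.02e-07) and BIC1 by 2.68 ± 0.19. BBX32 fell by 2.94 ± 0.37, RUP2 by 2.01 ± 0.19 and the HY5 homologue HYH by 1.32 ± 0.19. CHS (AT5G13930), the first enzyme of the flavonoid pathway, fell by 2.29 ± 0.30 (adjusted p = 0.000183), from 1.74 ± 0.19 to -0.55 ± 0.38 (SD, n = 3), and FLS1 fell by 2.41 ± 0.20. HY5 itself (log2 difference -0.94 ± 0.33, adjusted p = 0.0394) and COP1 (-0.51 ± 0.18, adjusted p = 0.041) stayed short of a 2-fold difference. Among genes with a symbol, the lowest values were in CYP706A6 (-6.05 ± 0.63), RK2 (-4.62) and PPT2 (-4.57).

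In total 1207 genes were higher and 1863 lower in wild type on 3B7N, 15% of the 20487 tested. A slide block gave 1248 and 1908, 2247 of them called in both fits with the same sign. All but 1 of the 3070 genes kept their sign within slide 1. That slide holds most of the arrays behind these calls, so the agreement of sign was largely fixed in advance. The share of called genes that were higher was 39.3%, and it was 52.7% (1539 higher and 1380 lower) with median scaling, which moved the median of all genes from -0.055 to 0.08. Normexp correction gave 789 higher and 826 lower.

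Of the lists, 13 of 22 PIF and shade genes were higher and 0 lower (median log2 difference 1.13, camera adjusted p = 1.03e-06, adjusted p = 0.185 with an estimated correlation). The same adjusted p = 0.185 with an estimated correlation was found for auxin response, xenobiotic detoxification, abscisic acid, dark and sugar starvation, photoprotection, cell wall expansion, and brassinosteroid and gibberellin. In auxin response 12 of 27 genes were higher (median 0.92, adjusted p = 1.05e-06), against YUC9, a gene of auxin synthesis, which fell by 1.304. In xenobiotic detoxification 12 of 32 were higher and 0 lower (median 0.85, adjusted p = 3.6e-08), led by the transporter gene ABCG40 (6.20 ± 0.36, at least 26.2-fold higher) and the glutathione transferase gene GSTU3 (AT2G29470, 3.75 ± 0.36, at least 3.63-fold higher, not called with normexp). In abscisic acid and water stress 8 of 12 were higher (median 1.39, adjusted p = 2.9e-05), with RD29B at 3.70 ± 0.32 and the cold-response gene COR15A against the rest at -2.13. In dark and sugar starvation 6 of 13 were higher (median 0.97, adjusted p = 8.02e-08), with BCAT2 at 3.18 ± 0.20. Photoprotection had 0 higher and 5 of 10 lower (median -0.93, adjusted p = 0.00514), with GPX7 at -3.14 (not called with normexp). Cell wall expansion had 7 of 24 higher and 3 lower (median 0.43, adjusted p = 0.00835), and the lower ones were EXPA1, EXPA10 and XTH20. Brassinosteroid and gibberellin had 4 of 30 higher and GA3OX2 lower (median 0.27, adjusted p = 0.00835).

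The flavonoid and anthocyanin pathway had 13 of 26 genes lower and 3 higher (4 higher when adjusted over the list alone). Its median was -1.13 (adjusted p = 0.00041, adjusted p = 0.306 with an estimated correlation). The 3 higher genes were the regulator MYB75 (2.47 ± 0.52), TT19 and 5MAT, all of the anthocyanin branch. Seed storage and lipid mobilisation had 5 of 14 higher (median 1.76, or 2.93 with a slide block, adjusted p = 0.00041, adjusted p = 0.34 with an estimated correlation), with the glyoxylate cycle gene ICL at 2.67 and EM1 at 3.46. Photoreceptors were shifted up (median 0.42, adjusted p = 0.00801, adjusted p = 0.23 with an estimated correlation) with PHYA higher and CRY3 lower. Photomorphogenesis regulators had 6 of 21 lower (median -0.52, adjusted p = 0.0183, adjusted p = 0.246 with an estimated correlation), and this call ended with a slide block (median -0.28, adjusted p = 0.0944). In every other list of this contrast the count adjusted over the list alone was the count over all genes. The remaining 3 calls were weak. Light harvesting (LHCB3 and LHCB4.2 higher and LHCB4.3 lower of 26, median 0.28, adjusted p = 0.0386, adjusted p = 0.664 with an estimated correlation) turned to a median of -0.02 with a slide block (0.075 with quantile scaling) and lost its call without DMSO array 1 (adjusted p = 0.0591), DMSO array 3 (0.07) or 3B7N array 2 (0.53). LHCB3 itself was not called with a slide block (0.92). Defence and jasmonate (4 of 19 higher, PR5, JAZ10, VSP1 and VSP2, median 0.27, adjusted p = 0.0201, adjusted p = 0.51 with an estimated correlation) lost it with a slide block (adjusted p = 0.0919) and without DMSO array 1 (0.182) or 3B7N array 2 (0.107), the arrays without which JAZ10 also lost its call. Cell division (0 of 14 called, median -0.33, adjusted p = 0.0258, adjusted p = 0.455 with an estimated correlation) lost it with median scaling (adjusted p = 0.0551) and without DMSO array 1 (0.0853) or 3B7N array 1 (0.0635).

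Lists without a call in wild type were ethylene (4 higher, 1 lower, adjusted p = 0.0665), the circadian clock (3 higher, 1 lower, 0.0911), nitrate assimilation and nitric oxide (1 higher, 4 lower, 0.188), reactive oxygen response (3 higher, 1 lower, 0.264), chlorophyll biosynthesis (2 higher, 1 lower, 0.841), root-preferred markers (3 higher, 1 lower, 0.61), glucosinolates (0 higher, 1 lower, 0.97) and housekeeping (0 called, 0.247). In the clock, PRR7 (1.98) and GI (1.89) rose while LHY fell by 2.17. In the nitrate list, the nitrite reductase gene NIR1 fell by 1.25, and GSR1, LBD38 and HB1 were lower too, while the glutamate dehydrogenase gene GDH1 rose by 1.197 (GSR1 and LBD38 lost the call with median scaling). Median and mean differed in sign for chlorophyll biosynthesis (-0.09 and 0.58, with PORA behind the mean) and root-preferred markers (-0.04 and 0.36), and the glucosinolate median (-0.06) opposed its test direction. Heat shock genes were higher on 3B7N in wild type (HSFA2 7.26 ± 1.25, adjusted p = 0.00102). HSP23.6-MITO (5.18) and HSP17.4 (4.80, at least 12.1-fold higher) lost the call with a slide block at about the same size (5.27, adjusted p = 0.0635, and 4.91, adjusted p = 0.0732).

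**Figure D2:**
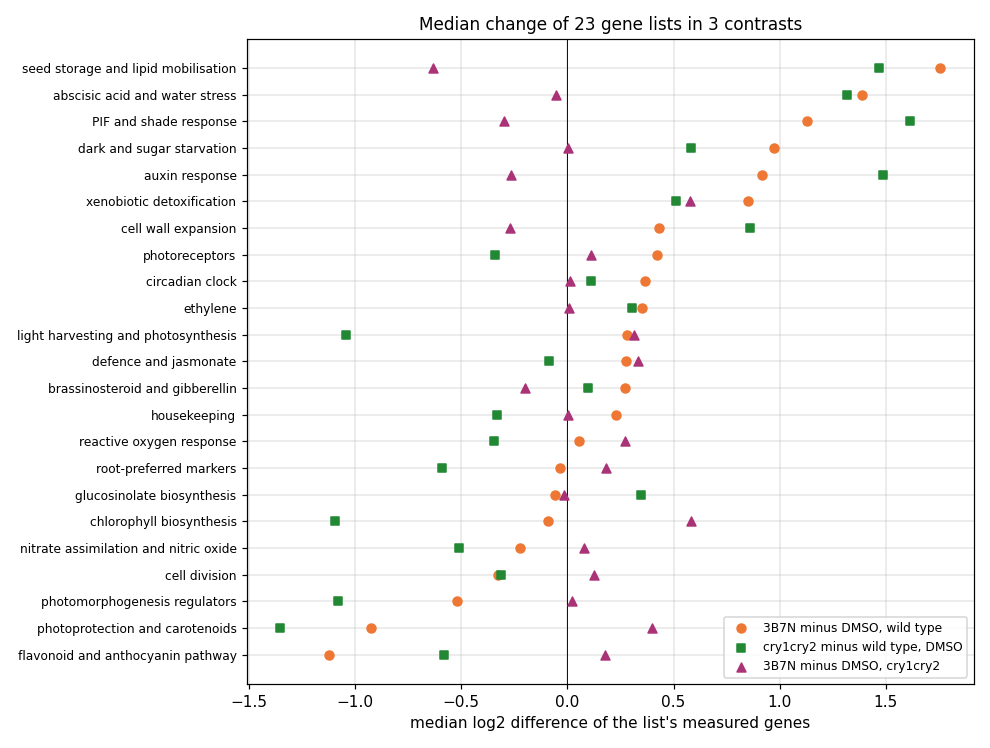
Median log2 difference of the measured genes of 23 lists in 3 contrasts (points, triangles and squares), without error bars. The PIF and shade list lies at 1.13 with 3B7N in wild type, 1.61 in the mutant against wild type and -0.30 with 3B7N in the mutant. With a slide block the light harvesting list in wild type turns from 0.28 to -0.02, and with quantile scaling the housekeeping list of the mutant contrast turns from -0.33 to 0.18.

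The second comparison asked how the mutant on DMSO differs from wild type. PIF4 was higher by 2.63 ± 0.23 (adjusted p = 4.08e-06), PIF5 by 1.63, PIF3 by 1.59, IAA19 by 3.87, IAA6 by 5.42, XTH17 by 4.51 and GA20OX1 by 4.40. PORA was higher by 11.48 ± 0.34 on its brightest probe (at least 1540-fold), by 8.765 on the second, which was above background on 2 of 3 wild-type DMSO arrays, and by 7.004 on the third (at least 86.8-fold). The transcription factor gene GRF7 (6.44 ± 0.29) and the vacuolar iron transporter gene VIT1 (6.11) were higher too. BBX32 was lower at -5.76 ± 0.37, BIC2 at -4.87 ± 0.21, BIC1 at -4.49 ± 0.19, CHS at -3.67 ± 0.30 (adjusted p = 2.86e-06), RUP2 at -3.35, F3H at -3.17 and HYH at -2.49 ± 0.19. Among genes with a symbol other than the cryptochromes, the lowest fitted values were ARGAH1 (-8.99, at least 102-fold lower), a locus close to CRY1, RK2 (-8.66, at least 87.7-fold lower) and CYP71A22 (-7.80, at least 79.3-fold lower). These rest on mutant signals at background, so their sizes and order are uncertain. HY5 (-0.72, adjusted p = 0.0953) and COP1 (-0.37, adjusted p = 0.114) were not called.

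In total 1562 genes were higher and 2333 lower in the mutant, 19% of those tested. With a slide block 1424 and 2355 were called, 2584 in both fits with the same sign, and HSFA2 (6.69, adjusted p = 0.0559) and ACS8 (2.35, adjusted p = 0.0913) then lost their calls. In light harvesting 15 of 26 were lower and 0 higher (median -1.04, adjusted p = 2.3e-05, adjusted p = 0.399 with an estimated correlation), with RCA at -1.70 and PSBS at -1.54, and quantile scaling ended this call (median -0.156, adjusted p = 0.0963). In chlorophyll biosynthesis 9 of 16 were lower against PORA (median -1.10, or -0.584 with quantile scaling, adjusted p = 0.00526, adjusted p = 0.399 with an estimated correlation), among them PORC (-1.34), HEMA1 (-1.29) and CHLG (-1.19).

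PIF and shade had 16 of 22 higher and 0 lower (median 1.61, adjusted p = 4.16e-09, adjusted p = 0.0841 with an estimated correlation), and auxin response 16 of 27 and 0 (median 1.49, adjusted p = 1.68e-06, adjusted p = 0.17 with an estimated correlation). Photoprotection had 8 of 10 lower (median -1.35, adjusted p = 2.52e-05, adjusted p = 0.108 with an estimated correlation). Photomorphogenesis regulators had 11 lower and BBX20 higher (median -1.08, or -0.49 with a slide block, adjusted p = 0.000241, adjusted p = 0.17 with an estimated correlation). Cell wall expansion had 11 higher and EXPA1 lower (median 0.86, adjusted p = 0.0018, adjusted p = 0.172 with an estimated correlation). The calls of the next 5 lists had an adjusted p = 0.399 with an estimated correlation. They were abscisic acid (8 higher, COR15A lower, adjusted p = 0.00106), dark and sugar starvation (4 higher, 0.00337), seed storage (5 higher, 0.00342, median 1.47, or 1.35 with members below background held at their bound, 0.637 with normexp and 3.15 with a slide block), flavonoids (10 lower and 2 higher, 11 and 4 adjusted over the list alone, 0.00754) and xenobiotic detoxification (7 higher, 2 lower, 0.0078). In the xenobiotic list UGT73C1 (-4.13) and UGT73C6 were the lower genes. Blocking by slide ended the calls of dark and sugar starvation (adjusted p = 0.0664) and xenobiotic detoxification (0.0739), and array weights that of seed storage (0.13). Ethylene was called at the threshold (4 higher, adjusted p = 0.0499, adjusted p = 0.199 with an estimated correlation) and lost the call in 13 alternatives (0.116 with a slide block), 6 of which left out 1 array (highest 0.0817, without wild-type DMSO array 1).

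Photoreceptors (2 higher, 4 lower with CRY1, CRY2, CRY3 and ZTL), brassinosteroid and gibberellin (7 higher, 2 lower), the clock (5 and 5), nitrate and nitric oxide (1 and 5), reactive oxygen (2 and 2), defence (4 and 1), glucosinolates (1 and 1), cell division (0 and 1), root-preferred markers (4 and 4) and housekeeping (0 and 0) were not called in this contrast. Medians and means differed in sign for the clock, reactive oxygen and defence lists. Among the nitrate genes GS2 was lower at -1.59 and HB1 higher at 1.73. Of the housekeeping genes UBQ10 (-0.92), GAPC2 (-0.88) and EF1A (-0.86) had the lowest values.

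The third comparison asked whether 3B7N changes the same genes where the cryptochromes are missing. Fewer genes were called, 431 higher and 334 lower (3.73%). GPAT6 (AT2G38110), an acyltransferase gene of cutin synthesis, rose by 3.95 ± 0.20 (adjusted p = 5.93e-07), and MYB93 (AT1G34670), a regulator expressed in root endodermis, by 3.81 ± 0.21. TBL4 rose by 4.50 ± 0.26 (at least 5.95-fold), MYB67 by 4.13 ± 0.38, the pathogenesis-related gene PR5 by 3.98 ± 0.33 and its neighbour TLP-3 by 3.92 ± 0.15. All 6 were also called higher in wild type, GPAT6 at 2.47, MYB93 at 2.045, TBL4 at 2.90, MYB67 at 2.54, PR5 at 2.93 and TLP-3 at 3.32. TBL4 and MYB67 were above background on 0 of 3 wild-type DMSO arrays. GSTU3 rose by 3.72 ± 0.36, as in wild type, and UGT73C1 by 3.72 ± 0.32. Each was higher on 3 of 3 treated arrays than on any mutant DMSO array. Of these TBL4, MYB67, PR5, GSTU3 and UGT73C1 were not called with normexp, the wild-type calls of TBL4, MYB67 and PR5 ended there too, and the genes named next stayed higher with each scaling (MYB53 at 0.72 and without a call with normexp). Among genes chosen after their values were seen, GPAT5 (2.19), GPAT7 (2.22), ABCG2 (2.81), ABCG6 (1.70), ABCG20 (2.07) and MYB53 (2.12) were higher too, with values of 2.52, 2.58, 2.88, 2.41, 2.304 and 2.03 within slide 3. In wild type GPAT5 (1.80), GPAT7 (1.135), ABCG2 (1.76), ABCG6 (2.07) and ABCG20 (1.007) were called higher as well, and MYB53 (0.62) was not called. The wild-type calls of GPAT7 and ABCG20 ended with normexp and with a slide block. MYB9 was higher in both (1.37 in wild type and 1.33 in the mutant, neither called with normexp), while GPAT8 fell in the mutant by 1.33 (adjusted p = 0.0134, not called with a slide block). No list of such genes was fixed or tested.

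UMAMIT36 fell by 4.37 ± 0.37 (adjusted p = 3.53e-05), GASA5 by 3.72 ± 0.47 (at least 3.65-fold, not called with normexp), GLR2.2 by 2.83 ± 0.29 and HEC3 by 2.93 ± 0.55. PAL1 (-1.70 ± 0.16) and CHI (-1.305 ± 0.17) fell in the mutant too, and the expansin gene EXPA2 fell by 1.71 ± 0.29. PIF4 (-0.35, adjusted p = 0.403), PIF5 (-0.17, adjusted p = 0.659), CHS (1.01 ± 0.30, adjusted p = 0.0648), HYH (0.89 ± 0.19, adjusted p = 0.0164), HY5 (-0.01, adjusted p = 0.993) and COP1 (-0.07) were not called in the mutant.

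These counts depended on slide and on single arrays. A slide block left 218 genes higher and 98 lower, 270 of them called in both fits with the same sign, and all 765 genes kept their sign within slide 3. Slide 3 holds most of the arrays behind the 765 calls, so that agreement of sign was largely fixed in advance. The lower genes numbered 148 without 3B7N array 1, 222 without DMSO array 3 and 510 without 3B7N array 2 of the mutant. The share higher was 56.3%, or 41.9% with normexp correction (134 higher and 186 lower).

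In the mutant, xenobiotic detoxification had 6 of 32 higher (7 adjusted over the list alone) and 0 lower (median 0.58, adjusted p = 4.08e-10, adjusted p = 0.151 with an estimated correlation). Chlorophyll biosynthesis was shifted up (median 0.58, adjusted p = 5.32e-07, adjusted p = 0.202 with an estimated correlation) with DVR (1.25) and PORC (1.05) called, both without a call with a slide block (adjusted p = 0.227 and 0.0575). Cell wall expansion had 5 of 24 lower and 0 higher (median -0.27, adjusted p = 8.02e-05, adjusted p = 0.151 with an estimated correlation), namely EXPA2, EXPA5, EXPA8, EXPA11 and XTH20. In the slide-block fit EXPA5, EXPA8 and EXPA11 were not called (adjusted p = 0.0989, 0.0998 and 0.0991). Photoprotection (2 higher, 3 adjusted over the list alone, median 0.40, adjusted p = 0.00206, adjusted p = 0.202 with an estimated correlation) held ELIP1 (2.19) and ELIP2 (1.70). The last 4 calls each ended without some single array. Light harvesting (0 genes called, median 0.31, or 0.141 with quantile scaling, adjusted p = 0.013, adjusted p = 0.837 with an estimated correlation) ended without DMSO array 1 (adjusted p = 0.595) or 3B7N array 1 (0.0512). PIF and shade (0 called, median -0.30, adjusted p = 0.0317, adjusted p = 0.519 with an estimated correlation) ended without DMSO array 2 (0.052), DMSO array 3 (0.0856) or 3B7N array 1 (0.0757). Brassinosteroid and gibberellin (0 called, median -0.20, adjusted p = 0.0317, adjusted p = 0.425 with an estimated correlation) ended with a slide block (0.0863) and without DMSO array 2 (0.0815), 3B7N array 1 (0.0512) or 3B7N array 3 (0.0553). Defence (PR5, FRK1 and PAD3 higher, of which FRK1 turned to -0.07 with normexp, median 0.33, or 0.034 with normexp, adjusted p = 0.0473, adjusted p = 0.837 with an estimated correlation) ended in 7 of the fits that left out 1 array, the highest 0.167 without DMSO array 2.

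Auxin response (0 called, median -0.27, adjusted p = 0.0876) and the other 14 lists were not called in the mutant. The flavonoid list had 3 lower and 0 higher (4 and 1 adjusted over the list alone), and its median (0.18) and mean (-0.08) differed in sign. Signs also differed for the clock, nitrate, dark and sugar, and housekeeping lists, and the ethylene median (0.005) opposed its test direction. Called members elsewhere were RAB18, HB1, MYB28 and SESA1 (lower) and OXI1, AOX1D and MLS (higher), and each of these but MLS lost its call with a slide block.

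The difference of the changes was tested as the interaction. It called 2602 genes higher (the change in the mutant lay above that in wild type) and 1211 lower, 18.6% of genes. Slide is partly aligned with this contrast. Of the 6 arrays that enter it negatively, 4 were on slide 2, against 0 of the others. With a slide block 1938 and 914 genes were called, 2109 in both fits with the same sign. PIF4 had an interaction of -3.00 ± 0.32 (adjusted p = 9.93e-05), IAA19 of -3.40, CHS of 3.297 ± 0.43 (adjusted p = 0.000311) and HYH of 2.22 ± 0.27 (adjusted p = 0.000227). PORA gave -9.48. For CYP71A22 (5.25) the mutant on DMSO was at background, which limits how far the gene can fall there. HY5 (0.93, adjusted p = 0.151) and COP1 (0.44, adjusted p = 0.218) were not called. Of the 3070 genes called with 3B7N in wild type, 2153 (70.1%) were called in the interaction with the opposite sign. The interaction subtracts the wild-type change by which these genes were chosen, so part of this share is built in. Median scaling moved the share higher from 68.2% to 56.5% (2074 higher and 1596 lower) and normexp to 57.5%. Normexp moved the median of all genes from 0.073 to -0.146.

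In the interaction PIF and shade (0 higher, 11 lower, 13 adjusted over the list alone, median -1.43, adjusted p = 6.21e-08, adjusted p = 0.111 with an estimated correlation) was lowest in p. Next, with equal adjusted p, came auxin response (0 and 14, 15 adjusted over the list alone, median -1.15, adjusted p = 1.48e-07, adjusted p = 0.128 with an estimated correlation) and dark and sugar starvation (0 and 7, median -1.28, or -0.808 with a slide block, adjusted p = 1.48e-07, adjusted p = 0.22 with an estimated correlation), both lower. So were abscisic acid (1 and 7, 1 and 10 adjusted over the list alone, median -1.45, adjusted p = 3.22e-05, adjusted p = 0.228 with an estimated correlation) and cell wall expansion (1 and 10, 2 and 10 adjusted over the list alone, median -1.02, adjusted p = 3.56e-05, adjusted p = 0.111 with an estimated correlation). Seed storage (0 and 5, median -2.28, or -4.135 with a slide block, adjusted p = 9.09e-05, adjusted p = 0.364 with an estimated correlation) and brassinosteroid and gibberellin (1 and 9, median -0.50, adjusted p = 0.000972, adjusted p = 0.135 with an estimated correlation) were lower. Higher were photoprotection (6 and 0, median 1.45, or 0.93 with normexp, adjusted p = 9.09e-05, adjusted p = 0.111 with an estimated correlation), flavonoids (12 and 3, median 0.95, adjusted p = 0.0103, adjusted p = 0.501 with an estimated correlation) and photomorphogenesis regulators (6 and 1, median 0.69, adjusted p = 0.027, adjusted p = 0.324 with an estimated correlation). The flavonoid median was -0.01 and the photomorphogenesis median 0.44 with normexp, and the photomorphogenesis call ended with a slide block (adjusted p = 0.129).

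Mutant and wild type on 3B7N differed in 821 higher and 670 lower genes (7.28%), against 3895 on DMSO. A slide block left 14 and 32, where the median SE was 0.325 against 0.185. The higher genes numbered 565 without 3B7N array 2 and 1035 without 3B7N array 1 of wild type, and the share higher was 55.1%, 36.1% with median scaling (560 higher and 991 lower) and 33% with normexp. Camera called 6 lists lower, of which light harvesting (0 higher, 14 lower, median -1.01, adjusted p = 3.96e-10, adjusted p = 0.431 with an estimated correlation) had most genes, and its call ended with quantile scaling (median -0.001, adjusted p = 0.25). Photoreceptors (0 and 4, median -0.48, adjusted p = 3.39e-07, adjusted p = 0.188 with an estimated correlation) hold the mutated CRY1 (-11.55) and CRY2 (-11.25, at least 1400-fold lower). Without both, in a test chosen after these values were seen, 2 of 12 were lower, ZTL and PHOT2 (median -0.404, adjusted p = 0.000543, adjusted p = 0.431 with an estimated correlation). Photomorphogenesis regulators (0 and 7, adjusted p = 0.000418, adjusted p = 0.32 with an estimated correlation) were lower too. The remaining 3 had an adjusted p = 0.431 with an estimated correlation. They were dark and sugar starvation (5.67e-05), housekeeping (0.00579, or 0.663 with quantile scaling, with UBQ10 called at -1.17) and the clock (0.0317, lost in 9 alternatives, 3 of which left out 1 array, the highest 0.116 without wild-type 3B7N array 1). Ethylene, not called, had 2 higher genes, 3 adjusted over the list alone. Median, mean or test direction differed in sign for flavonoids, auxin response, cell wall expansion and reactive oxygen in this contrast, and for light harvesting, defence and root-preferred markers in the interaction, none of them called there. With an estimated correlation camera called 0 lists in any contrast, while 4, 4, 5, 2 and 5 lists had an unadjusted p under 0.05 in the order wild type, mutant, genotype on DMSO, genotype on 3B7N and interaction.

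The change with 3B7N in wild type was then set against the other contrasts across the 20487 genes. With the mutant difference on DMSO, r was 0.696 (rho 0.646) and the covariance 0.606. Both contrasts share the wild-type DMSO arrays, and groups simulated without change gave r = 0.499 and a covariance of 0.0375. Genes higher in both numbered 676, against 92 for independent lists of those sizes (n1 × n2 / N), and genes lower in both 1070, against 212. Opposite calls numbered 24 and 41, against 137 and 142. Independent lists take no account of the shared arrays, so these are not the counts to be had without a change. Of the 1811 genes called in both, 96.4% had the same direction. Over all genes 74.1% had the same sign, against 66.7% in the groups simulated without change. With no array in common, using 1 DMSO array in the first contrast and the other 2 in the second, the covariance was 0.601, 0.579 and 0.537. With the change taken within slide 1 it was 0.641, 0.613 and 0.583. These values lie around the main covariance less the simulated one (0.568), on parts of 1 and 2 arrays. With the change in the mutant, with which no array is shared, r was 0.038 (rho -0.093) and the covariance 0.017. Over the 3070 genes called in wild type the slope of the mutant change on the wild-type change was 0.05, and 0.087 with a slide block. Of these genes 283 were called in the mutant in the same direction and 117 in the opposite one. Independent lists would give 25.4 genes higher in both, against 167 found, 30.4 lower in both, against 116, and for opposite calls 19.7 against 33 and 39.2 against 84.

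**Figure D3:**
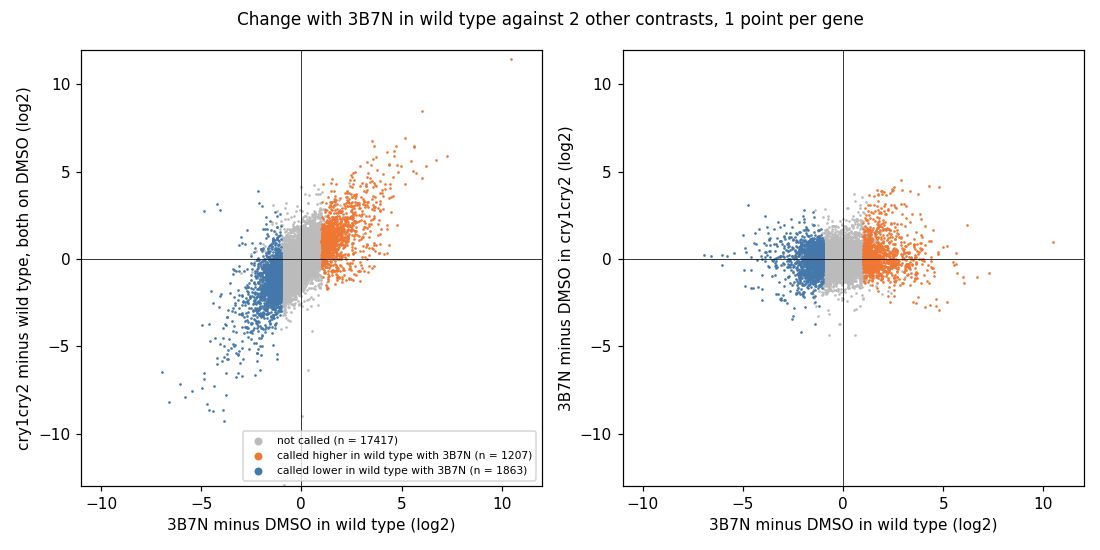
Log2 change with 3B7N in wild type (x axis) against the mutant minus wild-type difference on DMSO (left, y axis, log2) and against the change with 3B7N in the mutant (right), 1 point per gene, with genes called higher or lower in wild type coloured. The left cloud rises (r = 0.696, with shared DMSO arrays) and the right one is flat (r = 0.038).

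In the mutant, the change with 3B7N opposed the mutant difference on DMSO (r = -0.366, rho -0.401, covariance -0.194). The shared mutant DMSO arrays alone gave a simulated r of -0.5 and a covariance of -0.0376. Genes lower in the mutant and higher on 3B7N numbered 207, against 49.1 for independent lists, and genes higher in the mutant and lower on 3B7N 163, against 25.5. Here too the independent lists take no account of the shared arrays. Same-direction calls numbered 42 and 21, and of the 433 genes called in both 14.5% had the same direction. Over all genes 35.5% had the same sign, against 33.4% in the groups simulated without change. By sign alone the opposition was thus no stronger than the shared arrays give. With no array in common the covariance was -0.165, -0.139 and -0.168, the last of them within slide 3. The main covariance less the simulated one was -0.157.

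Most of the probes that the authors listed were also called in a fit to single probes, which called further probes. Their table held 3453 probes for wild type with folds of 2 to 149.3, of which 2030 were lower and 1423 higher in the present probe fit, and 91% were called there. For the mutant it held 577 probes with folds up to 16.26, 208 lower and 369 higher, of which 85.3% were called. The log2 sizes, from the same arrays, correlated across the listed probes at r = 0.999 and 1. The present fit called 4562 and 823 probes, of which 3141 and 492 were on the authors' lists. Of the called genes with several kept probes, 11 of 717 in wild type, 5 of 138 in the mutant and 20 of 969 between genotypes had a probe of the opposite sign.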

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

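The tests of heat shock genes, the splits with the effects of genotype and chemical taken out, the values with dim signals held at a floor and the slope of the mutant change on the wild-type change were chosen only after the result was seen, and the tests of shared arrays, slide and the remaining splits of the arrays were planned before.

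A difference between the genotypes in the change with 3B7N singled out most results here. By the interaction test 2602 genes lay higher and 1211 lower in the mutant's change than in that of wild type. With slide as a block these counts were 1938 and 914, and this contrast is partly aligned with slide. Among 100 random splits of the 12 arrays into 4 groups, 1 gave as many called genes, the real one with 3813, and the highest other split called 1437. These splits mix the effects of genotype and chemical into the spread, which may lower their counts. With both effects taken out first, 1 of 100 gave as many, the real one. Its count was thus larger than in the other random regroupings of these 12 arrays. The interaction itself stayed in those values and entered the spread of the other splits. Arrays were taken as exchangeable, so slide and samples from 1 culture are not covered, and chance is not excluded. The highest other then called 1667, and at an unadjusted p under 0.05 the real split gave 8492 genes and the highest other 6579.

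Among genes with a symbol, the highest fitted interactions were those of CYP706A6 (5.70 on the log2 scale), CYP71A22 (5.25), THI2.2 (5.24), TBL15 (4.91) and MYB62 (4.90). These genes fell with 3B7N in wild type and were already low in the mutant. Except for THI2.2, their sizes and order rest on signals near background. Of the 3 mutant arrays on DMSO and the 3 on 3B7N, 1 and 0 were above background for CYP706A6, 0 and 0 for CYP71A22, 1 and 3 for TBL15 and 0 and 2 for MYB62. With each signal held at the lowest level flagged above background on its array, the interaction was 4.96, 3.87, 3.203 and 1.246 in that order. With normexp CYP706A6 and CYP71A22 lost the call and MYB62 turned to -0.185. The lowest fitted ones were PORA (-9.48), HSFA2 (-8.05), ENODL1 (-7.74), HSP17.4 (-7.73) and HSP23.6-MITO (-7.62). In wild type on DMSO, 0 of 3 arrays were above background for the brightest PORA probe and for HSP17.4 and 1 for HSP23.6-MITO (a dimmer PORA probe was on 2), and with signals held as above their interactions were -8.598, -6.523 and -6.891, so their sizes and order are uncertain. HSFA2, HSP17.4 and HSP23.6-MITO lost the call with a slide block. Of the genes fixed in advance, CHS (3.297) and HYH (2.22) were higher and PIF5 (-1.80) and PIF4 (-3.00) lower.

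Of the gene lists, the interaction medians were 0.688 for photomorphogenesis regulators, 0.951 for flavonoids and 1.45 for photoprotection. They were -1.145 for auxin response, -1.427 for PIF and shade, -1.02 for cell wall expansion, -0.50 for brassinosteroid and gibberellin, -1.445 for abscisic acid, -1.28 for dark and sugar starvation and -2.282 for seed storage. With normexp the flavonoid median was -0.005, that of photoprotection 0.93 and that of photomorphogenesis regulators 0.44. With a slide block dark and sugar starvation stood at -0.808 and seed storage at -4.135.

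In wild type on 3B7N the called genes as a set moved toward their level in the mutant, and in the mutant they did not move that way. Over the 15333 genes called in neither contrast r was 0.495. That is near the 0.499 which shared arrays gave over all genes without a change, so the shift is shown for the called genes. Noise of single shared DMSO arrays accounts for little of this shift. With no array in common, at least 88.6% of the covariance with the mutant difference was kept. Slide alone accounts for little either, since at least 96.2% was kept within slide 1, on 1 treated array. Neither check removes a deviation common to all 3 wild-type DMSO arrays, which would enter both contrasts, so that stays open. Over the genes called in wild type, the slope of the mutant's change on the wild-type change was 0.05, or 0.087 with a slide block, which is consistent with a response that needs the cryptochromes. That the mutant's genes already stand at the level which 3B7N brings about, so that a separate pathway with the same targets has no room left, stays open and was not tested.

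Heat shock genes were high with 3B7N in wild type and also on single mutant arrays. Of 23 HSP genes 8 were called higher with 3B7N in wild type and 1 lower, and the median difference of all 23 was 0.98, of which at least 71.31% was kept with any 1 array left out. The share kept over all 23 genes argues against a single array as the whole cause. For the 8 HSP genes called higher between genotypes on DMSO, the median was 4.23 and at least 90.73% was kept. That choice shared the wild-type DMSO arrays with this difference, and all arrays entered its estimate of the spread. It is therefore no independent check on single arrays. The 2 sets of 8 share 6 genes, and the levels given next are those of the set called in wild type. In the mutant the mean level reached 2.66 on DMSO array 2 against -1.39 and -2.31, and 0.10 on 3B7N array 3 against -3.42 and -3.32. The larger of these ranges is 119.32% of the difference between the wild-type groups (4.17). Over all 23 genes, which were not chosen by their change in wild type, it is 158.51% of that difference (1.64). Handling of single samples may thus also have moved these genes in wild type. A response to 3B7N stays open, since over all 23 genes the lowest treated wild-type array lay 1.08 above the highest DMSO array.

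Probes without a matched locus, which entered no gene test, also changed. Of 4255 tested, 531 were called with 3B7N in wild type (257 higher, 274 lower), 80 in the mutant (55 and 25) and 811 between genotypes on DMSO (329 and 482). No explanation was tested for them.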

How the results depend on the processing

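Slide as a random block and leaving out mutant DMSO array 2 with 3B7N array 3 were chosen only after the data were seen, and all other alternatives were planned. Apart from the changes given here, the counts per contrast and direction stayed within 1.5 times their value. Of the comparisons of named genes with the alternatives, 13224 kept their side of the threshold, 553 lost a call, 174 gained one and 6 reversed. Of those of gene lists 2762 were the same, 138 lost a call, 67 gained one and 0 reversed. Direction was compared only where a fit made a call, so a change of sign without a call counts as kept. Slide and scan pass gave the same fits. Leaving out an array outside a contrast changes only its spread, so these totals do not count independent checks. Contrasts are given as wild type on 3B7N, mutant on 3B7N, genotype on DMSO, genotype on 3B7N, and interaction.

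Normexp gave 789 higher and 826 lower in wild type on 3B7N, 134 and 186 in the mutant, 1009 and 1445 between genotypes on DMSO, 187 and 379 on 3B7N, and 1164 higher in the interaction. It adds an offset that shrinks dim probes, and it also starts from the raw median signal in place of the processed one. Which of these lowered the counts was not tested, and values of dim genes are uncertain. It reversed AOX1D (-0.068) and FRK1 (-0.066) in the mutant on 3B7N, FRK1 (-0.614) between genotypes on 3B7N, and FRK1 (-0.502), MYB28 (-0.333) and MYB62 (-0.185) in the interaction. The cause was not tested. A filter on all 12 arrays tested fewer genes and left 287 and 206 in the mutant and 453 higher between genotypes on 3B7N. No filter gave 1929 lower in the last, for which the cause was not tested.

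A slide block, like the scan pass, gave 218 and 98 in the mutant and 14 and 32 between genotypes on 3B7N, where the median SE rose from 0.185 to 0.246 and 0.325. As a random block slide gave 418 and 319, and 701 and 614. The replicate number as a block gave 1189 and 1857, 412 and 316, 1537 and 2319, 798 and 655, and 2575 and 1184, and camera then called 15, 7, 12, 6 and 10 lists. The number did not pair the samples, since only 6 of 18 pairs of arrays with the same number correlated over 0.1 (-0.325 to 0.358) after group means were removed. Leaving out the 2 mutant arrays left 199 lower in the mutant, on fewer samples.

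Thresholds moved counts by their construction. Adjusted p alone gave 3371 and 4815, 951 and 605, 4043 and 5080, 2901 and 2434, and 2234 lower in the interaction. An adjusted p under 0.01 gave 276 and 149 in the mutant and 467 higher between genotypes on 3B7N. Treat gave 181 and 79 in the mutant, 154 and 220 between genotypes on 3B7N, and 1407 and 647 in the interaction. Camera with an estimated correlation called 0 lists in each of the 5 contrasts, and quantile scaling 3 between genotypes on 3B7N (the cause was not tested).

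Leaving out 1 array gave 1115 to 1316 higher and 1657 to 2091 lower in wild type, 295 to 461 and 148 to 510 in the mutant, 1446 to 1682 and 2265 to 2429 between genotypes on DMSO, 565 to 1035 and 573 to 727 on 3B7N, and 2320 to 2725 and 1013 to 1253 in the interaction. The mutant's lower genes numbered 148 without 3B7N array 1, 222 without DMSO array 3 and 510 without 3B7N array 2. Camera called 12 to 16, 4 to 10, 12 to 16, 5 to 7 and 10 to 14 lists, with 4 in the mutant without 3B7N array 1.

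The correlation of the wild-type change with the mutant difference (0.696) was 0.557 without a filter, 0.778 with a slide or scan-pass block, 0.495 over genes called in neither contrast and 0.891 over genes called in both, and 0.642 to 0.719 with 1 array left out. Its sets of genes differ by construction. With slide or scan pass as a block, 1 part of the fitted mutant difference is the wild-type change itself. The other part compares the mutant on DMSO with wild type on 3B7N within the slide they share. The 0.778 is thus partly built in and does not show a closer resemblance. For the remaining values the cause was not tested. The correlation of the wild-type change with the change in the mutant (0.038) ran from -0.093 to 0.08 over the alternatives and from -0.019 to 0.138 with 1 array left out.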

Other observations

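The test by families of gene symbols, the genes of secondary walls and the loci next to the cryptochrome genes were chosen only after the result was seen, while the tests of shared arrays, slide and other splits were planned before.

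The exact test takes the members of a family as independent, and members that vary together can make its p-values too small. Among families, ABCG transporters stood out with 3B7N in both genotypes. In wild type 14 of 34 were higher and 2 lower (2.3 higher for chance, Fisher's exact adjusted p = 6.15e-06) and in the mutant 8 of 34 (adjusted p = 7.8e-05), with 12 and 6 in a slide block. In wild type SAUR genes were also higher by the exact test (6 of 13, adjusted p = 0.0114, but 4 with normexp and 4 with a slide block). So were IAA genes (7 of 21, 0.0271, with 3 lower, but 5 higher with normexp). HSP genes were higher too (8 of 23, 0.0114, with 1 lower, but 1 higher with a slide block and 3 with normexp). Of the members 6 SAUR and 7 IAA genes were on the fixed lists, so these 2 tests partly repeat the auxin list. In the mutant on DMSO 20 of 59 NAC genes were higher than in wild type and 2 lower (1.59e-05 for higher, exact test). In the mutant on 3B7N the secondary-wall genes IRX1 (-1.37), IRX3 (-1.24), IRX6 (-1.60), IRX9 (-1.28) and IRX15 (-1.66) were lower, with LAC17 (-1.285), MYB46 (-1.42) and MYB85 (-2.31). These had been higher in the mutant on DMSO, as IRX15 at 2.47 and MYB85 at 4.11, whereas MYB83 (-1.03) and MYB63 (-1.117) were lower with 3B7N but had not been called higher on DMSO (0.71 and 0.21). With normexp IRX1, IRX15, LAC17, MYB63, MYB83 and MYB85 (-1.435) were not called. The family test gave 5 of 10 IRX genes lower (exact adjusted p = 7.8e-05), 3 with normexp and 0 with a slide block, where their values within slide 3 ran from -1.05 (IRX3) to -1.73 (IRX15). Of these 5, with 1 mutant array left out, 1 stayed called without DMSO array 1 or 3B7N array 1, 2 without DMSO array 2, DMSO array 3 or 3B7N array 3, and 5 without 3B7N array 2. On that array the genes stayed near the DMSO level, IRX15 at -2.19 against -4.31 and -4.28 on the other treated arrays and IRX1 at 0.46 against -0.90 and -0.94. Laccase genes went both ways in the mutant on 3B7N, 5 of 13 higher and 4 lower, or 4 and 1 with a slide block and 3 and 3 with normexp.

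The change with 3B7N in the mutant opposed the mutant's difference from wild type. The shared mutant DMSO arrays produce such an opposition by themselves, with a simulated r of -0.5 against -0.366 here. By sign the opposition was no stronger than theirs, with 35.5% of genes of the same sign against 33.4%. With no array in common at least 71.6% of the covariance was kept. Parting the arrays does not remove a deviation common to all mutant DMSO arrays. Within slide 3, on 1 DMSO array, 86.6% was kept, which argues against slide as the whole cause. A partial return of the mutant toward wild type by 3B7N is a candidate explanation, found on the same data and not tested in other samples. For the IRX genes the calls between genotypes and with 3B7N ended with a slide block while the sizes moved little. IRX15 went from -1.66 ± 0.43 to -1.73 ± 0.67 with 3B7N and from 2.47 ± 0.43 to 2.28 ± 0.89 between genotypes, so the larger SE ended its calls. Mutant DMSO array 3, on slide 3, had IRX15 at -1.86, against -1.82 and -2.12 on arrays 1 and 2 of slide 2. Treated array 2, also on slide 3, stood at -2.19. The DMSO level of IRX15 was thus not confined to slide 2, but this rests on single arrays and does not exclude slide.

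Some genes listed beside the cryptochromes were also low in the mutant. By the order of loci, ARGAH1 (-8.99 ± 0.35) and AT4G08910 (-5.72) lie just before CRY1, and APRL6 (-0.81) and AT4G08940 (-0.34), neither called, just after it. ARGAH1 was at background in the mutant on DMSO, so its fitted size is uncertain. Next to CRY2, c-NAD-MDH1 stood at -6.36 ± 0.19 and AT1G04420 at -12.92 ± 0.36, and the next locus, AT1G04430, at 0.18. Before CRY2, AT1G04350 (-2.69) and AT1G04360 (-1.91) were lower too, and the 2 loci between them and CRY2 were not tested. On 3B7N the mutant's values were -8.95 for ARGAH1, -4.29 for AT4G08910, -7.08 for c-NAD-MDH1, -11.97 for AT1G04420 and -1.385 for AT1G04350, while AT1G04360 stood at 0.409 (adjusted p = 0.0873, not called). Whether the lesions of the mutant reach past CRY1 and CRY2 was not tested and stays open, so the low values of these neighbours are not shown to follow from the loss of the cryptochromes.

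Each contrast of 3 arrays against 3 has 10 splits, too few for a share under 0.05. In fits of the 6 arrays alone, 1 of 10 splits, the real one, called 3023 genes with 3B7N in wild type, 718 in the mutant, 3907 between genotypes on DMSO and 1457 on 3B7N. The highest of the other splits called 0 by limma in each of the 4 contrasts. These splits put arrays of both groups on each side, so the real difference enters their spread and keeps their counts low. At an unadjusted p under 0.05 the real splits gave 9135, 4735, 10591 and 7509 genes and the highest others 672, 1566, 610 and 1001. By that threshold 1024 genes would be expected without any difference.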
